A study of Caenorhabditis elegans with 2 samples.

How the data were processed

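Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole young adult hermaphrodites of a transgenic Caenorhabditis elegans strain that carries an insertion of F23B12.7 fused to GFP, with an antibody against GFP. The strain also has an unc-119 mutation in its genotype. There was 1 group, with 2 biological replicates as numbered in the labels, so no groups were compared. The files used were peak lists. The alignments and signal tracks were not used here.

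For each replicate, and for the reads of both replicates pooled, the authors deposited a list of 30000 peaks and background regions, called against a control and meant as input for a test of reproducibility. They also deposited the peaks that passed an irreproducible discovery rate (IDR) threshold, called IDR peaks below. Each list came in the genome builds ce10 and ce11. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here, nor is it stated whether the control was input DNA or another immunoprecipitation. The signal value of each peak is the authors' own, on a scale that may differ between lists, so its values were not compared between lists. Signal was used to describe, rank or select peaks within a list and was correlated between the replicates. Each list also holds the authors' deposited −log10 q-values, which ranked peaks in 1 alternative. The lists hold no read totals, so the depth of each replicate is unknown, and no interval that needs depth is given. The per-peak score column and the p-value column of the lists each held a single value and were not used. The summit of each peak was taken from the offset that the authors deposited with it.

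The ce11 lists were annotated, since all 7 chromosomes of the lists fit the chromosome lengths of the reference assembly WBcel235, which is the same build. The ce10 lists were used for peak counts and the overlap of the replicates. Genes came from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. Names missing there were taken from the RefSeq annotation of the same assembly. For mitochondrial genes the RefSeq symbol of the gene with the same span was used. The gene start is the 5′ end of the annotated gene. In this species many annotated 5′ ends are sites of trans-splicing, so transcription can begin further upstream.

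The following choices were made before the data were examined. A peak was placed at a promoter when its summit lay within 500 bp of a protein-coding start, and otherwise in an exon, an intron or between genes. The promoter share was compared with 10000 rotations of all nuclear peaks along their chromosomes, one-sided, which keep the spacing of peaks. The share of peaks on each of the 6 chromosomes was set against the share of protein-coding promoters there with an exact two-sided binomial test. For 16 gene lists chosen by gene name, the members with a peak within 500 bp of their start were compared with all other protein-coding genes by a two-sided Fisher's exact test. For 4 classes of RNA gene, the number of genes with a peak within 250 bp was compared with the same rotations, one-sided. Sequences of 101 bp centred on the summits were compared with windows centred 500 bp to the left, by an exact McNemar test for each of 2080 6-mers, with both strands read as 1 sequence. The motifs CCAAT, CACGTG and GAGA were named in advance. In each of these families the p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The smallest p that the rotations can give is 0.0001. Peaks of the 2 replicates were matched by an overlap of at least 1 bp, and the overlap of their strongest peaks was compared with 1000 rotations. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which treat peaks or genes as independent and cover counting error only.

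The genes named are those nearest to the 15 peaks of highest signal, where a start lies within 500 bp, the 4 members of highest signal of each list or RNA class with more peaks, the 2 of highest signal of each list with fewer, and F23B12.7 and unc-119. Because 14 of those 15 peaks were mitochondrial, the strongest nuclear peaks were also named, a choice made after their values were seen. The 6-mers named, with the smallest p-values, were also picked after their values were seen. The 23 mitochondrial IDR peaks were left out of the comparisons, which concern nuclear genes. Of the name patterns of the lists, 7 matched no gene. No gene was in more than 1 list.

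Alternatives were the ce10 list, the IDR peaks above the median signal, merging of overlapping peaks, the strongest peaks of either replicate alone, removal of peaks near F23B12.7 and unc-119, other distances, other backgrounds and tests for the gene lists, chromosome length as the reference, other rules for matching replicates, and other control windows. Added after the data were seen were RNA genes over 1000 bp from a coding start, removal of peaks at tRNA genes, control windows matched for GC content and the ce10 overlap of replicates. Promoters without a peak were read 200 bp upstream of the start, a distance picked after the median position of the summits was seen.

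The tests were tried on simulated data. With 1700 simulated peaks placed at random, the promoter test passed the threshold in 4 of 100 runs, and in 20 of 20 runs with 40 percent of the peaks planted at starts. Over 19973 genes, 3 of 1600 list tests passed with no list planted. All 140 planted lists with 40 percent of members hit were recovered, as were all 60 lists with no member hit. Of 20 planted 6-mers, 20 were recovered, with 37 of the 2060 other 6-mers called in the same run, and none of 2080 was called when none was planted. Both sets of simulated windows had the same base composition, whereas the summit and control windows differed in GC content. These runs therefore do not show how many 6-mer calls follow from composition. In the list runs genes were hit independently, whereas neighbouring genes can share a peak. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.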

Results

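The experiment looked for regions of chromatin recovered with a GFP fusion of F23B12.7 from young adult hermaphrodite worms, taken as whole animals. Chromatin was sheared by sonication, DNA was recovered with an antibody against GFP, and enriched regions were called as peaks. Both samples were biological replicates of 1 group, so the results below describe 1 set of peaks, set against the rest of the genome, and hold no comparison between conditions. Depth is unknown for both samples. All coordinates are in ce11.

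The set held 1707 IDR peaks, of which 1684 were on the nuclear chromosomes and 23 on the mitochondrial genome. The strongest nuclear peak lay at rpl-3, which encodes a protein of the large ribosomal subunit, with a signal value of 310 on the authors' scale (chromosome III, 3867463 to 3867728). It was followed by a peak at cdc-48.1, which encodes an AAA ATPase that unfolds ubiquitinated proteins, with a signal of 281 (chromosome II, 10563464 to 10563685). The ribosomal protein genes rpl-15, rpl-20 and rpl-35 were also at peaks of high signal, 238, 237 and 222. The rpl-20 peak was nearer to the start of the neighbouring gene Y17G9B.5. The peak ranked just below that of cdc-48.1 had a signal of 245 and no coding start within 500 bp (chromosome III, 8043866 to 8044070). The median nuclear signal was 52.2, with a lowest value of 37.99. The ce11 set was the 1707 peaks of highest signal in the pooled list, and all of them were in that list with the same coordinates and signal. Of all IDR peaks, 1661 had a width of 356 bp. Merging overlapping peaks left 1694 regions.

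Of the 15 peaks of highest signal, 14 were mitochondrial, and the exception was the rpl-3 peak. The highest of all had a signal of 2417 and lay at the start of CYTB, the gene of cytochrome b (4412 to 4933 of the mitochondrial genome). The nearest protein-coding starts to further peaks were those of ND2 (617), COX1 (536 and 309), COX2 (483), ATP6 (449), ND4L (404), ND4 (375), ND3 (349), COX3 (325) and ND1 (298), which encode subunits of respiratory complexes and of ATP synthase. The other 3, with signals of 1088, 790 and 631, had no protein-coding start within 500 bp (12835 to 13369, 12247 to 12528 and 10421 to 10661). Starts of mitochondrial RNA genes were not searched. The summits of the 1088 and 790 peaks lay inside ND5, and that of the 631 peak inside WBGene00014472, a gene without a symbol. The peak of signal 298, nearest to the start of ND1, had its summit inside WBGene00014454, also without a symbol. The median mitochondrial signal was 325. IDR peaks covered 47.2% of the mitochondrial genome and 0.591% of the nuclear chromosomes.

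The tagged gene was examined first as a check of the labels, since a transgene copy can give signal without binding. F23B12.7 (chromosome V, 14449697 to 14452976) had no IDR peak within 500 bp of its start. Within 20 kb of the gene there were 2 IDR peaks, at the starts of coh-3 (signal 60.6) and F08H9.3 (signal 63.3). As many or more peaks lay within 20 kb of 19.9% of protein-coding genes. The unc-119 gene (chromosome III, 10902641 to 10908935) had no IDR peak within 500 bp of its start and 1 within 20 kb, at the start of com-1 (signal 44.96). As many or more lay within 20 kb of 50.01% of genes. The kind of control is unknown, and a control from the same strain would carry the same transgene. The absence of a peak at these genes therefore does not decide whether the labels are right.

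Peaks lay mostly just upstream of protein-coding genes. Of the 1684 nuclear peaks, 1007 had their summit within 500 bp of a coding start (59.8%, 95% interval 57.4 to 62.2%). Rotating the peaks along their chromosomes placed 18.5% there on average and 25.2% at most, so the observed share was 3.23 times the mean (permutation test by rotation, one-sided, p = 0.0001, the smallest the rotations can give). In all, 1342 of 19973 protein-coding genes (6.72%) had a peak within reach. The summit was upstream of the start in 92.0% of these genes, with a median position of −191.5 bp. Exons held 3.15% of the peaks (95% interval 2.37 to 4.10%), against 22.7% after rotation. Introns held 15.97% (14.3 to 17.8%) against 29.7%, and 21.1% lay between genes (19.2 to 23.1%) against 29.1%. These class shares carry no test. The exon share was 4.88% with the strongest peaks of replicate 2 alone.

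**Figure D1:**
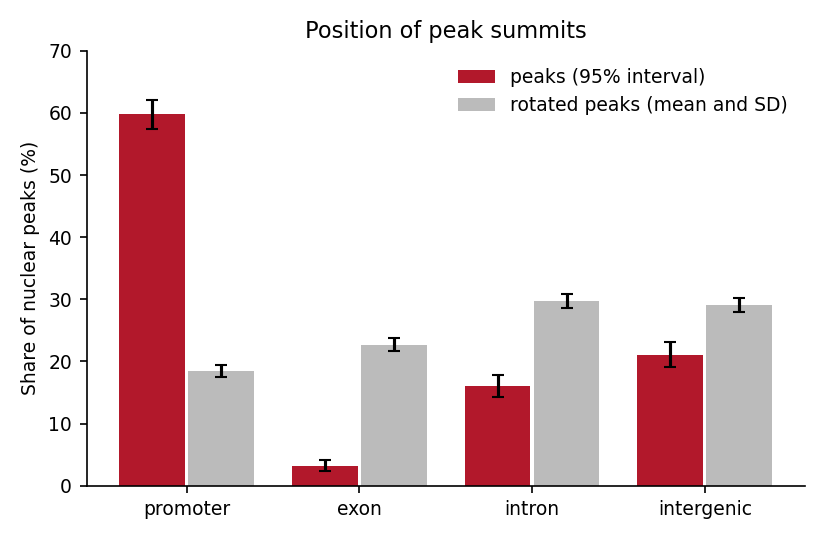
Share of the 1684 nuclear peaks (%, vertical axis) whose summit fell in each annotation class (horizontal axis). Red bars are the observed shares with 95% exact binomial intervals and grey bars are the mean and SD over 10000 rotations, with 59.8% of peaks and 18.5% of rotated peaks at promoters.

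Genes of the protein synthesis machinery carried peaks far more often than other genes. Of the 83 genes of cytosolic ribosomal proteins, 67 had a peak at their start (80.7%, 95% interval 70.6 to 88.6%), 12.6 times the share of other genes (Fisher's exact test, adjusted p = 1.64e-62). The strongest were rpl-3, rpl-15, rpl-20 and rpl-35, and the median summit of the list lay upstream of the start, at −280 bp. Among translation factors, 24 of 43 had a peak (8.44 times, adjusted exact p = 7.27e-17), with the highest signal at eef-1G (145), eef-1A.1 (133), iff-2 (115.02) and eif-3.C (107). These encode subunits of elongation factor 1, a counterpart of initiation factor 5A and a subunit of initiation factor 3. Mitochondrial ribosomal proteins had 19 of 70 (4.08 times, adjusted exact p = 2.47e-07), led by mrpl-49 (93.5), mrps-17 (82.6), mrps-7 (77.4) and mrpl-17 (68.1). Genes of ribosome biogenesis and RNA polymerase I had 11 of 33 (4.99 times, adjusted exact p = 1.18e-05). Among these, utp-20 had a signal of 111.8, fib-1, which encodes the nucleolar methyltransferase fibrillarin, 83.7, lpd-7 68.5 and nol-10 67.6. The aminoacyl-tRNA synthetases, which load tRNAs with amino acids, had 3 of 31, 1.44 times the share of other genes, and did not pass the test (adjusted exact p = 0.528). Among genes with any peak of the pooled list in reach, the folds were 4.89 for cytosolic ribosomal proteins, 3.85 for translation factors, 2.27 for ribosome biogenesis, 1.89 for mitochondrial ribosomal proteins (adjusted exact p = 0.00870 for each of the last 2) and 0.722 for the synthetases, and without possible operon members the synthetases had 0.704. The fold of the cytosolic ribosomal proteins was 5.84 at 250 bp and 22.4 with the peaks above the median signal, that of the synthetases was 2.30 at 250 bp, and against rotated peaks the folds were 14.4 to 43.6 for the 4 lists that passed and 5.31 for the synthetases, which did not pass there either. Rotation moved peaks away from promoters (59.8% observed, 18.5% after rotation). Folds against rotated peaks were therefore higher for all 16 lists and are not a comparison with other genes.

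Other housekeeping groups carried peaks too. Mitochondrial respiration had 24 of 43 nuclear genes with a peak (8.44 times, Fisher's exact test, adjusted p = 7.27e-17), with signals of 156 at cox-5A, 136 at cox-5B, 124 at atp-1 and 117 at atp-3, which encode subunits of cytochrome c oxidase and ATP synthase. The proteasome had 17 of 33 (7.75 times, adjusted exact p = 1.75e-11), led by rpn-9 (91.9), pbs-3 (82.3), rpn-3 (72.3) and rpn-5 (65.9). The core spliceosome had 18 of 43 (6.30 times, adjusted exact p = 2.70e-10), where rsp-5 and snr-3 are divergent neighbours at the same peak (signal 101.1), followed by prp-40 (92.6) and rsp-1 (81.6). Chaperones had 18 of 61 (4.44 times, adjusted exact p = 1.52e-07), led by dnj-9 (97.1), cct-8 (93.0), hsp-6 (92.4) and dnj-11 (92.1). The germline and oocyte list had 15 of 80 (2.81 times, adjusted exact p = 0.000424), with puf-9 (80.7), a Pumilio family gene known to act outside the germline too, cpg-1 (72.0), egg-1 (68.4) and cpg-2 (59.7) highest. That call did not hold among genes with any peak of the pooled list in reach (1.52 times, adjusted exact p = 0.115) or with the IDR peaks above the median signal (2.10 times, adjusted exact p = 0.0973). The histone genes had 5 of 81 (0.918 times, adjusted exact p = 1), with 0.603 times for the strongest peaks of replicate 2 alone, and their ratio was over 1 in 4 alternatives, up to 4.02 in the rotation test, none past the threshold. Among genes with a pooled peak in reach, the folds of the other lists here were 3.85 for respiration, 3.17 for the proteasome, 2.87 for the spliceosome and 2.14 for chaperones (adjusted exact p at most 0.00211). With the nearest start alone, chaperones had 2.63 times and the spliceosome 4.20 times, and against rotated peaks the 5 lists that passed had 10.6 to 30.3 times the mean. The values against rotated peaks here, that of histones included, have the same lower baseline at promoters.

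Of the 5 lists of genes used in other tissues, 4 had fewer genes with a peak than other genes. The muscle list, with 2 of 40 (0.744 times, adjusted exact p = 1), did not pass, and had 0.407 times with the strongest peaks of replicate 2 alone, 0 at 250 bp and 3.06 times the mean in the rotation test. The neuron list had 1 of 143 genes with a peak, at snb-1, which encodes synaptobrevin (0.103 times the share of other genes, Fisher's exact test, adjusted p = 0.00161). The intestine list had 2 of 198, gst-27 and act-5 (0.149 times, adjusted exact p = 0.000424), and the sperm list had 1 of 94, spe-48 (0.158 times, adjusted exact p = 0.0260). The list of cuticle and hypodermis had 7 of 253 (0.409 times, adjusted exact p = 0.0102), with the highest signal at the collagen genes col-38 (121) and col-2 (94.4). Rotated peaks could not test the first 3 for fewer genes, since they met only 1.61 (sperm) to 2.89 (intestine) members on average and even a count of 0 would have had an unadjusted permutation p of 0.114 or more. The counts were 0.428 (neuron), 0.692 (intestine) and 0.620 (sperm) times those means, and for cuticle 1.70 times the mean of 4.11 (adjusted permutation p = 0.316). Since rotation moved peaks away from promoters, ratios over 1 for cuticle and muscle do not show more peaks than at other genes. The strongest peaks of replicate 2 alone gave 0.577 times for cuticle (adjusted exact p = 0.137) and 0.410 times for intestine (adjusted exact p = 0.0469), and replicate 1 alone gave 0.234 times for intestine (adjusted exact p = 0.00278). The sperm call was also lost at 250 and 1000 bp, with the nearest start alone and without possible operon members, with 0.185 to 0.501 times and adjusted p-values from 0.0523 to 0.218 in those exact tests. With the peaks above the median signal, sperm (0.296 times, adjusted exact p = 0.355) and cuticle (0.660 times, adjusted exact p = 0.449) did not pass. Among genes with a pooled peak in reach, neuron (0.212 times, adjusted exact p = 0.113), sperm (0.461 times, adjusted exact p = 0.807) and cuticle (0.560 times, adjusted exact p = 0.152) did not. The neuron ratio was 0.164 at 1000 bp. At 250 bp cuticle had 0.0928 times, and neuron had no gene with a peak there, nor with replicate 2 alone or the peaks above the median signal.

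**Figure D2:**
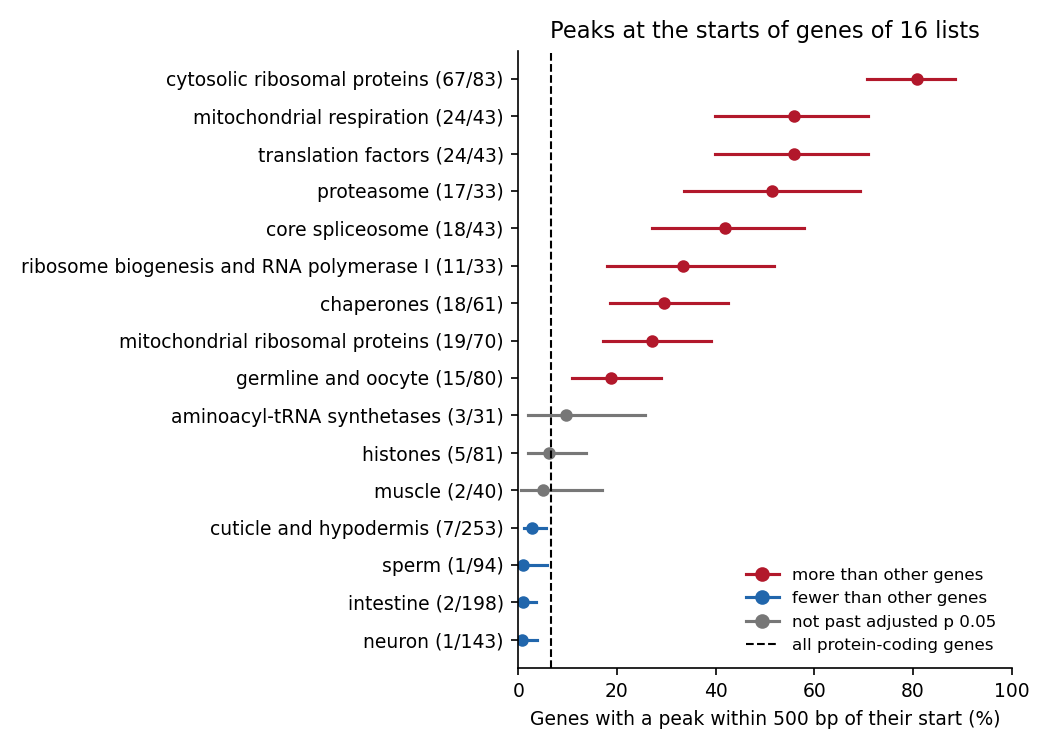
Share of the genes of each of 16 lists with an IDR peak within 500 bp of the start (%, horizontal axis), with 95% exact binomial intervals as lines and the counts beside each name. Red lists had more and blue lists fewer genes with a peak than other genes at an adjusted p under 0.05, and the dashed line is the share over all protein-coding genes, 6.72%.

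Genes of small noncoding RNAs were the other large class at the peaks. Of 612 nuclear tRNA genes, 294 had a peak within 250 bp (48.0%, 95% interval 44.0 to 52.1%), 51.3 times the mean of the rotations. Of 346 snoRNA genes, which guide the modification of other RNAs, 87 had one (25.1%, 22.6 times). Of 129 snRNA genes, which include the spliceosomal and spliced leader RNAs, 25 had one (19.4%, 19.6 times). For each of these 3 classes the adjusted p was 0.000133, from a permutation p of 0.0001, the smallest the rotations can give. The folds depended on the reach: within 125 bp they were 87.3 for tRNA, 35.9 for snoRNA and 32.5 for snRNA genes, and within 500 bp 28.4, 14.5 and 11.3. The peaks above the median signal gave 36.5 for snoRNA genes. None of the 20 nuclear rRNA genes had a peak (95% upper bound 16.8%), where the rotations gave 0.288 on average, so the test could not have shown fewer. Among the 79 snRNA genes over 1000 bp from any coding start, 7 had a peak, 9.32 times the mean of the rotations. Summits at tRNA genes lay around the middle of the gene, at a median of −16 bp from it and with quartiles of −43.9 and 20.5 bp. Among tRNA genes the highest signal was at C18A11.t2 (136), at M02F4.t1 and M02F4.t2, which share a peak (126), and at T23F1.t1 (111). The summits of these peaks lay outside the named genes, at 175, −83.5, −104.5 and 68 bp from their middles in the same order. Among snoRNA genes it was at F54E7.10 (148), T06C12.16 (146), F11A10.9 and ZK484.9 (both 128). Among snRNA genes it was at sls-2.1 (153), sls-2.4 (151), sls-2.8 (119.1) and F38E11.11 (114). The F54E7.10 peak did not reach the gene, with a summit −313.5 bp from its middle. Of the 87 snoRNA genes with a peak, 19 (21.8%) lay within 500 bp of a coding start. Among the 203 snoRNA genes over 1000 bp from any coding start, 48 had a peak, 21.3 times the mean of the rotations. The tRNA genes hold sequence shared between copies. Of the 25 tRNA genes with no 36-mer found elsewhere in the genome, none had a peak, against 294 of the other 587. Of the 143 tRNA genes whose whole sequence was in no other nuclear tRNA gene, 43 had one (30.1%), against 251 of the other 469 (53.5%). All 43 held some repeated 36-mer. With 250 bp on each side, the tRNA genes with a peak had a median of 9.47% of repeated 36-mers. These last comparisons were chosen after the result was seen. The values do not decide whether shared reads contributed to the peaks.

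**Figure D3:**
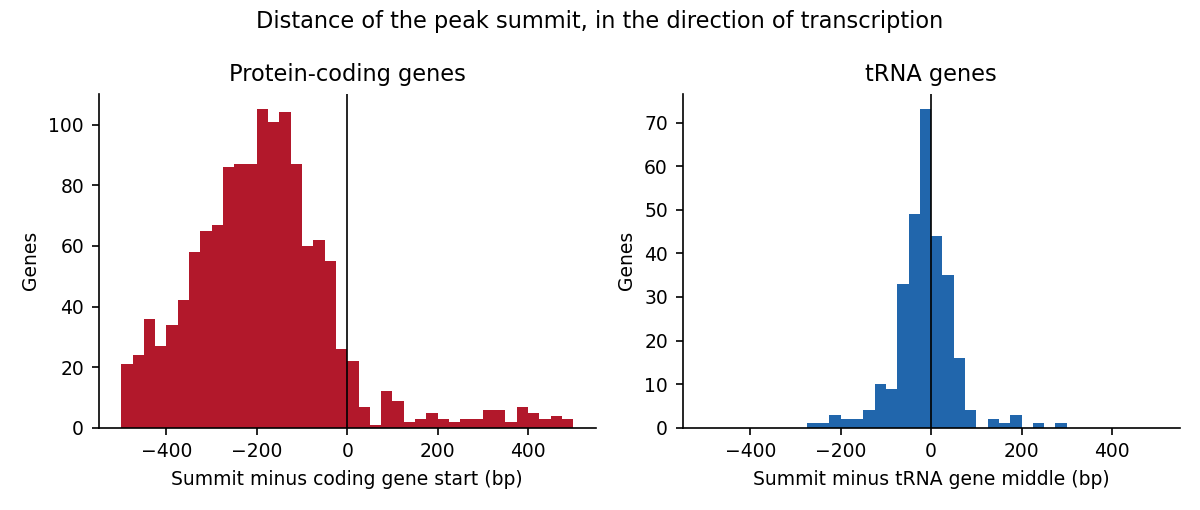
Position of the peak summit relative to the start of the 1342 protein-coding genes with a peak (left) and to the middle of the 294 tRNA genes with a peak (right), in bp along the direction of transcription (horizontal axes), as numbers of genes per 25 bp (vertical axes). Summits at coding genes lay upstream, with a median of −191.5 bp, and those at tRNA genes centred on the gene, with a median of −16 bp.

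Peaks at coding starts with no RNA gene of these classes numbered 937, and 303 peaks were at an RNA gene with no coding start in reach. A further 70 were at both, and 374, or 22.2% of nuclear peaks, were at neither.

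The chromosomes differed in their share of peaks. Chromosome III had 19.3% of the peaks and 13.2% of protein-coding promoters (exact binomial test, adjusted p = 9.23e-12), and chromosome I had 17.3% and 14.4% (adjusted p = 0.00171). Chromosome V had 14.1% of the peaks and 25.004% of the promoters (adjusted exact p = 3.19e-27). The X chromosome had 15.7% and 13.7% (adjusted exact p = 0.0237). Chromosomes II (16.1% and 17.3%) and IV (17.5% and 16.4%) did not pass the test, both with an adjusted exact p of 0.250, and II had 1.056 times its share of bases while IV had 0.990 times its share of promoters among the peaks above the median signal and 0.997 times with replicate 1 alone. The call on X was lost with the peaks above the median signal (1.17 times, adjusted exact p = 0.0820), and its direction turned when chromosome length was the reference (0.891 times its share of bases, adjusted exact p = 0.0567), and when peaks at tRNA genes were left out (0.808 times its share of promoters, adjusted exact p = 0.00562). The test treats peaks as independent, although neighbouring peaks can share a region.

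The strongest peaks of the replicates overlapped in part. When the 1707 strongest peaks were taken from each replicate, 58.5% of the nuclear ones of replicate 1 overlapped one of replicate 2, against 1.19% on average and 2.08% at most over 1000 rotations. Of the 1684 nuclear IDR peaks, all among those of highest pooled signal, 1682 overlapped a peak in the full list of replicate 1 and 1676 in that of replicate 2. Of these IDR peaks, 81.8% were in the strongest set of replicate 1 and 71.1% in that of replicate 2. In all, 56.8% of them were in both of these strongest sets and 3.98% in neither. At 1674 IDR peaks matched in both, Spearman's rho of the signal was 0.354 across peaks, which are not independent replicates and were selected on the combined signal, a selection that can lower rho. It was 0.361 at coding starts with no RNA gene, 0.365 at tRNA genes and 0.0495 at the peaks near neither, with a Pearson's r of the log2 signal of 0.387, 0.324 and 0.259 in the same order. Ranked by q-value instead of signal, rho over all matched peaks was −0.107, with most ranks tied. Over the 13971 nuclear peaks of the pooled list matched in both replicates, rho of the signal was 0.504.

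**Figure D4:**
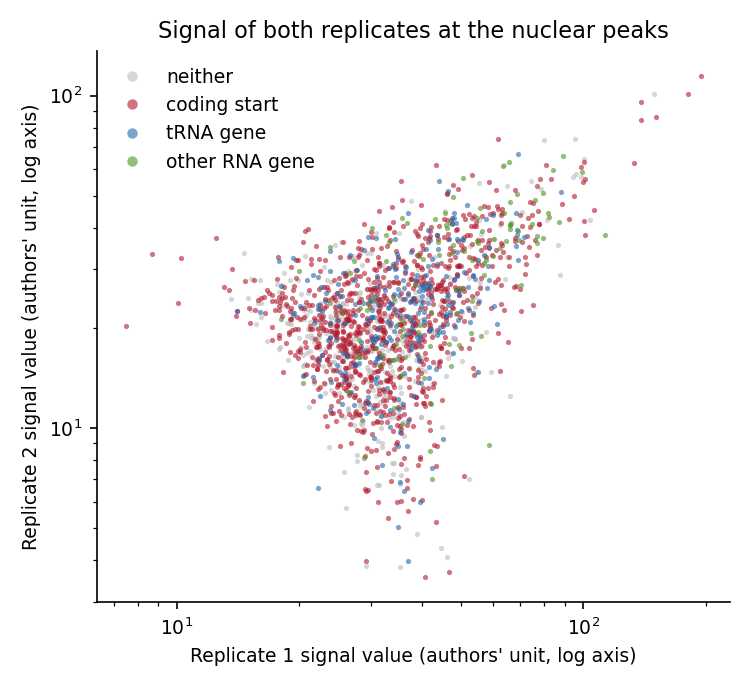
Signal value of replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis), each on the authors' scale for that list, at the 1674 nuclear IDR peaks matched in both. Each point is a peak, coloured by what lies at its summit, and rho over all points is 0.354.

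The sequence at the summits was rich in GC. The windows of 50 bp on each side of a summit held 45.6% ± 8.34 G and C (SD over 1684 peaks), against 37.2% ± 8.95 in the windows centred 500 bp away. Of 2080 6-mers, 511 occurred in more summit windows than control windows and 485 in fewer (exact McNemar tests, adjusted over all 6-mers). The most distinct was ACGCGC, in 250 summit windows and 14 control windows (adjusted exact p = 1.93e-54), followed by GAGCGC, in 237 and 31 (adjusted exact p = 1.71e-39). CTGAAA was in 138 and 426 (adjusted exact p = 8.63e-39). Of the motifs named in advance, CCAAT, chosen because a human counterpart of the protein is named for it, was in fewer summit windows, 15.8% against 20.1% (adjusted exact p = 0.00209). GAGA was in more, 68.3% against 57.5% (adjusted exact p = 5.09e-10). The E-box CACGTG, in 3.15% and 2.08%, did not pass (1.51 times, adjusted exact p = 0.0662). It passed with control windows on the right (1.96 times, adjusted exact p = 0.00337), against promoters without a peak (1.96 times, adjusted exact p = 0.00657) and without peaks at tRNA genes (1.77 times, adjusted exact p = 0.0140). With random windows of the same GC content its ratio was 1.04 (adjusted exact p = 0.921), and it did not pass with 100 bp on each side (1.25 times) or the peaks above the median signal (1.24 times). The ratio of ACGCGC windows, 17.9 here, was 6.41 to 10.1 with other controls or wider windows and 43.3 with the peaks above the median signal. With random windows of the same GC content, the ratio fell from 7.65 to 4.74 for GAGCGC and moved from 0.324 to 0.633 for CTGAAA (adjusted exact p = 7.34e-05). With 100 bp on each side these were 4.24 and 0.508, and CTGAAA had 0.531 against promoters without a peak. With the GC-matched windows, 336 6-mers were more frequent at summits, 257 of them among the 511.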

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

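The mitochondrial genome was outside the comparisons of nuclear genes, yet 23 IDR peaks lay on it, among them 14 of the 15 of highest signal. The lowest of the 23 had a signal of 79.2, under the highest nuclear value of 310. No biological explanation of these peaks was tested, since the design has no second group. The test of coverage by the pooled list was chosen only after the result was seen, and the test of shared reads was set out before. Reads shared with nuclear copies of mitochondrial DNA are argued against, because 0% of the 5842 distinct 36-mers in these peaks occur on the nuclear chromosomes. The peak at 4412 to 4933 was highest in both replicates, with signals of 1476 and 966. Signal spread over the whole of an abundant genome stays open without an immunoprecipitation from worms lacking the fusion, not analysed here. Peaks of the pooled list covered 51.0% of it, which decides nothing, since the IDR peaks alone covered 47.2%.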

How the results depend on the processing

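Across all alternatives, 296 of 354 values kept their direction and their side of the threshold, or moved by less than their margin, 24 moved by more and 15 turned direction. Of those 15, 11 were past the threshold in neither setting. A further 16 fell short of the threshold, mostly for the sperm, cuticle, neuron and germline lists, and 3 newly passed it, all for CACGTG. The number of gene lists with more peaks was 8 or 9, and that of RNA classes with more genes at peaks was 3, under every alternative run for them. The promoter share passed the rotation test throughout, at 41.2% to 70.3%. The 296 were not separate checks. Removing the peaks near F23B12.7 (2) and unc-119 (1) gave 35 of them, and summary counts were tallied beside the values they sum. Depth limits are unknown, since the lists give no read totals. Some alternatives were chosen after the data were seen: those without peaks at tRNA genes, with RNA genes far from coding starts, with matched GC content and with the ce10 overlap of replicates.

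Peaks above the median signal numbered 853, with 1.69% in exons and 2 lists with fewer peaks. With the reach at 250 bp, 41.2% of peaks were at promoters, 18.8% in introns and 36.05% between genes, and with it at 1000 bp these were 70.3%, 12.8% and 14.8%, with 2.08% in exons. This follows from the distance itself. With 1 replicate left out, the promoter share was 55.4% to 57.6%, the exon share 4.45% to 4.88% and the intergenic share 22.0% to 23.1%. Without peaks at tRNA genes, 67.7% were at promoters, 11.3% in introns and 17.5% between genes, which follows from where those genes lie. Lists with fewer peaks numbered 0 in the rotation test, which could not show fewer for sperm, neuron and intestine, with means of 1.61 to 2.89 genes, and 1 among genes with a pooled peak in reach. In the rotation test the cuticle list turned to 1.70, histones to 4.02 and muscle to 3.06 times the expected count. Rotated peaks lay at promoters less often (18.5% against 59.8% observed), so these 3 values do not show more peaks than at other genes. Histones also turned to 1.38 with the peaks above the median signal, 1.17 at 250 bp and 1.39 among genes with a pooled peak in reach, where the aminoacyl-tRNA synthetases turned to 0.722, and these turned to 0.704 without possible operon members. The share of peaks on X turned to 0.891 times that of bases and, without peaks at tRNA genes, to 0.808 times that of promoters. Chromosome II turned to 1.056 and 1.015 times in those settings, and IV to 0.990 with the peaks above the median signal and 0.997 without replicate 2, while it had 1.05 without replicate 1. The replicate overlap was 55.7% when the overlap had to cover 0.5 of both peaks and 55.2% with 3414 peaks taken from each replicate; the cause was not tested. The correlation of the replicates turned to −0.107 by q-value, a column that ranks the strongest peaks poorly, since 1707 of 1707 in replicate 1 and 1703 in replicate 2 had its highest value. With matched GC content, 336 6-mers were more frequent at summits. Within 10 kb of F23B12.7 there was 1 peak, and within 40 kb of unc-119 there were 3.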

Other observations

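The spliced leader RNA genes, which supply the short exon that worms trans-splice to many messenger RNAs, were counted by family. Of 18 sls-2 genes, which make the SL2 leaders used in operons, 10 had a peak within 250 bp, and the strongest of them, sls-2.1, had a signal of 153. Of 12 sls-1 genes, none had one. Among all other snRNA genes 15 of 99 had one. These families were separated after their values were seen, and the difference was not tested.

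On X, 108 of the 265 peaks (40.8%) were at tRNA genes, against 8.12% to 13.3% on the autosomes. X has 276 of the 612 nuclear tRNA genes, and 44.6% of them had a peak, within the range of 43.6% to 59.4% over the autosomes.

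Among the nuclear IDR peaks, 27 did not have the width of 356 bp, and the 27 held no repeated 36-mer, as was the case for 1311 of the 1657 peaks of that width.

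The tests in the rest of this part on the housekeeping lists, the comparison of tRNA genes by their whole sequence and the share of repeats around tRNA genes were chosen only after the result was seen.

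The absence of peaks at the 20 rRNA genes and the 12 SL1 genes was weighed against shared sequence. Signal that was present but under the IDR threshold was looked for in the pooled list of 30000 peaks. There, 0 of these 32 genes had a peak within 250 bp. This does not decide the question, since few or no peaks could be called there if shared reads were left out. Reads shared between copies may account for the absence: over these genes with 250 bp on each side, a median of 99.3% of 36-mers occur more than once in the genome, against 9.48% over the tRNA genes with the same flanks. The 1 of the 32 genes with no repeated 36-mer had no peak either. How the authors treated reads that map to several places is not given in the sources used here, and no biological explanation was tested.

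For the peaks at tRNA and ribosomal protein genes, nearness of tRNA genes to coding starts is argued against, since among the 421 tRNA genes over 1000 bp from any coding start the number with a peak was still 50.6 times the rotation mean. Reads shared between tRNA copies could contribute, as 0% of the 25 tRNA genes without repeated 36-mers had a peak (95% interval up to 13.7%). Single-copy genes may also be less active. Of the 143 tRNA genes whose whole sequence was in no other nuclear tRNA gene, 43 had a peak (30.1%). All 43 held some repeated 36-mer, so this share does not argue against shared reads. Around the tRNA genes with a peak, with 250 bp on each side, a median of 9.47% of 36-mers were repeated. Most of that window is flank, so this share does not limit what shared reads could add at the genes themselves. Over all tRNA genes without flanks the median was 100%, so a contribution there stays open. A contribution of shared reads would need at least some of them to be kept, whereas leaving them out could remove peaks at rRNA and SL1 genes. The treatment of such reads is unknown, so neither was tested. Signal that arises at active promoters whatever the protein is also open, as all 5 housekeeping lists outside the ribosome had more genes with a peak, and no immunoprecipitation without the fusion was analysed here. Binding of F23B12.7 itself is the biological alternative, and the design does not separate it from that.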
